A study of Azumapecten farreri with 9 samples.

How the data were processed

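RNA of scallop hemocytes was sequenced in 9 poly(A) libraries, paired-end, per the labels' protocols, with a kit that does not mark strand. Per the submitters' processing notes, HISAT, StringTie and edgeR were used, with no versions; the genome build and the counting settings are not given in the sources used here. The deposited table holds, per the file headers, an estimated count and an FPKM (fragments scaled by gene length and depth, by the authors) per gene and library, beside scaffold positions and gene descriptions. The counts are called estimated because low values pile up near multiples of 3.58 to 3.87; these expected counts were rounded to whole numbers. Which counter made them is not given. Genes that share reads with a close copy, such as actins, tubulins and heat shock proteins, and overlapping or antisense genes, are uncertain in their split.

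Groups were taken from the titles, because the titles and group labels of 6 libraries contradict each other. The planned test was limma on log2(FPKM + 1) unless the file also held counts; it did, so edgeR 4.0.16 was used (TMM scaling, quasi-likelihood test, 1 mean per group, all 9 libraries) and limma 3.58.1 became an alternative, as planned. Genes with an FPKM of at least 1 in at least 3 libraries were tested, with a Benjamini-Hochberg adjusted p under 0.05. Gene lists fixed before the data were examined were matched to descriptions, since the table has no symbols and the symbol patterns could not be used; 29 with at least 5 tested genes went into camera with a preset correlation of 0.01. Fisher's exact test, one-sided, was run on 1069 of the table's own GO and KEGG terms of 10 to 500 tested genes. Principal components and list medians used log2 CPM with a prior count of 2.

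The text names genes by a rule fixed before the data were examined. Per contrast it takes the 8 largest changes each way among named, called genes with non-overlapping FPKM ranges and a mean FPKM of at least 1 (chance gives non-overlap in 10% of genes for 3 libraries against 3), and the 2 members of each list with the smallest adjusted p. The chaperonin subunits other than theta were chosen after their values were seen. The plot of gene lists shows gene-centred medians, chosen after the medians of levels were seen to follow single genes in the actin list. A gene without a count in a group is given as a bound, against a floor of 3 fragments per library, which covers counting error only. Counts of 11678 genes were simulated once, with known changes of 0.5, 1 and 2 on the log2 scale in 66, 67 and 67 genes. LPS_T against PBS recovered 31.8%, 71.6% and 91.0% of these, with 7.80% of calls false. For both exosome groups against PBS these were 42.4%, 79.1% and 94.0%, with 8.28% false. Both false shares lay above 5% in this single run, whose spread was not measured. Far more genes were called in the data, so these rates do not carry over directly.

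Alternatives were other scalings, pseudocounts, filters, DESeq2 1.42.0, a replicate block, library weights, each library left out, an estimated correlation and other term sizes. Library pairs were checked for duplicates by a chi-square value per gene, after dividing counts by the estimated counts per fragment. Its median within groups was 2.15 to 2.88 times that of sampling noise. That ratio depends on the estimated counts per fragment, and no p-value was computed. R 4.3.3 and matplotlib 3.10.9 were used. No reference genome was used here.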

Results

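Hemocytes, the circulating immune cells of molluscs, were profiled by poly(A) RNA sequencing in the Zhikong scallop. The animals had been injected with PBS or with exosomes, small membrane vesicles released by cells, and the question stated in the series is how exosomes modulate immunity. There were 9 libraries in 3 groups of 3. The titles and the group labels of the 6 exosome libraries contradict each other: libraries titled LPS_T carry the label for normal exosomes, and those titled NOR_T the label for exosomes from LPS (bacterial lipopolysaccharide) stimulation. Groups are therefore named by title only, and no direction is assigned to LPS stimulation. The mean of both exosome groups against PBS does not depend on which label is right. No label says whether the libraries of a group came from separate animals or pools, so p-values measure the spread between these libraries, which may be technical.

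Estimated counts per library summed to between 19894628 (PBS 1) and 45831950 (PBS 3). One sequenced fragment was worth about 3.58 to 3.87 counts, which puts the depth at about 5220000 to 12200000 fragments. Of 21617 genes, 11678 passed the expression filter and were tested. Spearman correlations between libraries were 0.952 to 0.975 within groups and 0.909 to 0.941 between groups. PBS 1 stood apart: 17.8% of its counts fell on 2 adjacent genes of scaffold38697, against 0.0318% to 0.0979% in the other 8 libraries. It had 9865 genes at an FPKM of at least 1, against 10537 to 11341 elsewhere. Below, levels are CPM (counts scaled to library size by TMM), given as mean ± SD over the 3 libraries of a group (n = 3). Fold changes are log2 with an approximate standard error (SE). That SE is the absolute change divided by the square root of the F statistic of the quasi-likelihood test, not a separate estimate.

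**Figure D1:**
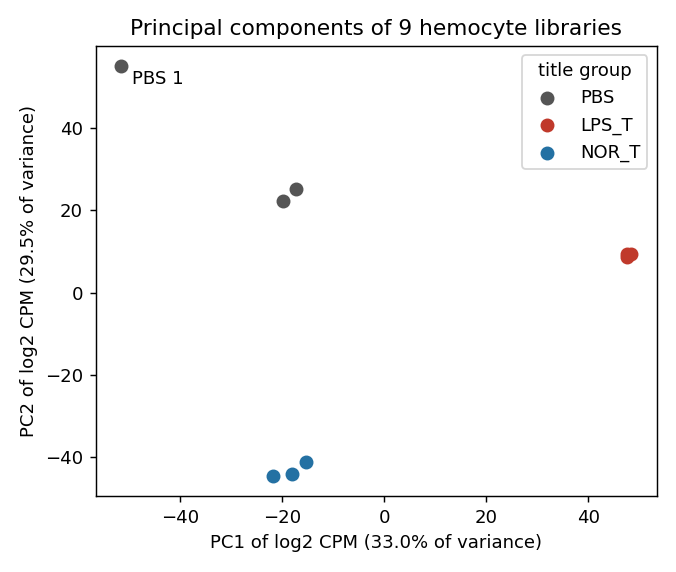
Principal components of log2 CPM over the tested genes, with 1 point per library coloured by title group. The axes hold 33.0% and 29.5% of the variance, the 3 groups lie apart, and PBS 1 lies away from the other PBS libraries.

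The first comparison asked what injection of either exosome preparation changed relative to PBS, as the mean of both exosome groups. All 8 subunits of the cytosolic chaperonin, a ring complex that folds actin and tubulin, fell, with log2 changes from -1.53 to -1.16 (edgeR, largest adjusted p = 4.92e-08); as a complex they were singled out after their values were seen. T-complex protein 1 subunit theta-like (evm.TU.scaffold17381.1) stood at 629.6 ± 6.07 CPM in PBS, 186 ± 5.21 in LPS_T and 279 ± 18.7 in NOR_T, a change of -1.47 (SE 0.05); the gene lies at positions 7555 to 20075 of its scaffold, minus strand. Heat shock 70 kDa protein 4-like (evm.TU.scaffold17795.23), an HSP110-type co-chaperone, went from 754 ± 18.2 CPM to 308 ± 2.75 and 329.8 ± 3.18 (-1.24, SE 0.04, adjusted p = 2.25e-12).

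**Figure D2:**
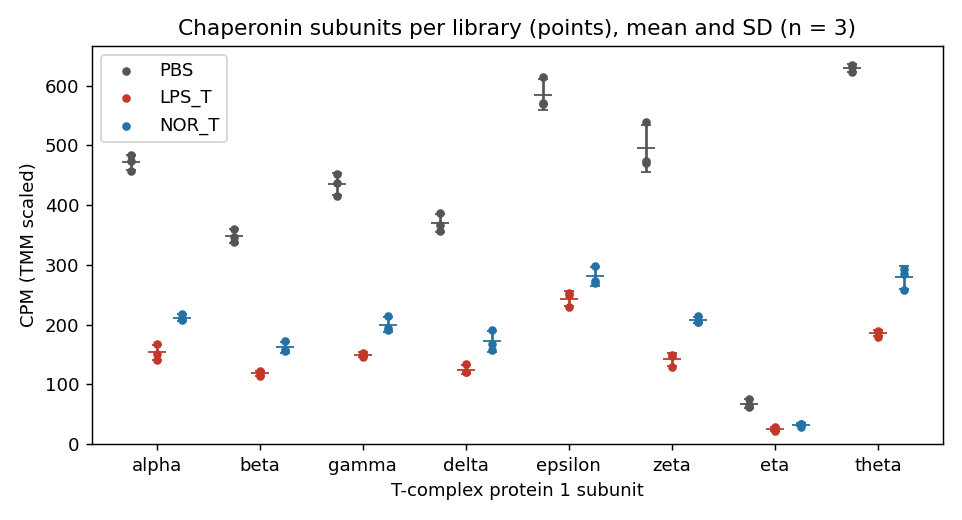
CPM of the 8 T-complex protein 1 subunits in each of the 9 libraries (points), with the mean and SD of each title group (n = 3). Every subunit was lower in both exosome groups than in PBS, by log2 changes of -1.53 to -1.16 for the mean of both groups.

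Of 12 tested members of the list of endoplasmic reticulum (ER) stress and protein folding, 9 fell and 0 rose (camera adjusted p = 4.77e-07; adjusted p = 0.230 with an estimated correlation). They included 78 kDa glucose-regulated protein-like (evm.TU.scaffold38447.14), the ER chaperone BiP, at 2678 ± 36.4 CPM in PBS against 1136 ± 11.2 and 1925 ± 108, and calreticulin-like (evm.TU.scaffold42613.16), a calcium-binding ER chaperone, with a change of -0.79 (SE 0.05). In the list of heat shock proteins and chaperones, 25 of 80 members fell and 12 rose (camera adjusted p = 0.0151; adjusted p = 0.557 with an estimated correlation; 13 higher and 28 lower adjusted over the list alone). Its median change was near 0 (-0.00253) and its mean -0.23, so no direction is given for the list as a whole. The median was 0.0779 with library-size scaling only and 0.13 in limma on unscaled log2(FPKM + 1). In these settings the median of all tested genes moved too, to 0.0978 and 0.15. Its call was lost without PBS 1 (camera adjusted p = 0.0563), with library weights (0.101) and with no filter on low values (0.189). Of the ribosomal proteins, 36 of 124 were lower and 4 higher, with a median of -0.14 (camera adjusted p = 2.31e-05, and 0.557 with an estimated correlation). In LPS_T 54 were lower and in NOR_T 10. On unscaled FPKM the list lost its call (camera adjusted p = 0.230), and its median was 0.0243, where that of all tested genes was 0.15. 40S ribosomal protein S19 (evm.TU.scaffold59391.12) changed by -0.25 (SE 0.05), a call lost on unscaled FPKM and with library-size scaling only.

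In the list of actin cytoskeleton and adhesion, 22 of 46 members rose and 4 fell (camera adjusted p = 5.86e-04; adjusted p = 0.230 with an estimated correlation; 24 higher and 4 lower adjusted over the list alone), with a median change of 0.23. The median of the members' levels, which follows the gene in the middle of the list, went the other way, from 5.44 ± 0.27 log2 CPM in PBS to 5.33 ± 0.06 in LPS_T and 5.10 ± 0.10 in NOR_T. Profilin-like (evm.TU.scaffold41425.24), an actin-monomer binding protein, went from 139.8 ± 7.86 CPM to 287 ± 9.32 and 264 ± 9.25. Actin-2 (evm.TU.scaffold14907.6) changed by 1.31 (SE 0.09, adjusted p = 1.42e-08). Among the annotation terms of the file, actin binding held more higher genes than expected (30 of 77, adjusted p = 7.56e-04), and protein folding more lower ones (29 of 65, adjusted p = 6.20e-06). Lower genes were also enriched among G-protein coupled receptors (20 of 40, adjusted p = 3.68e-05) and the phagosome (33 of 99, adjusted p = 3.33e-04). Against PBS by single group, neither term was called in both. The receptor term was called lower in LPS_T only (19 of 40, Fisher's exact test, adjusted p = 2.26e-04). The phagosome term was called lower in NOR_T only (30 of 99, Fisher's exact test, adjusted p = 4.38e-04). In the cell cycle list 7 of 27 members rose and 1 fell (camera adjusted p = 0.00982; adjusted p = 0.553 with an estimated correlation). Its call was lost without PBS 1 (camera adjusted p = 0.0547) and with library weights (0.0650).

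Immune genes moved both ways. In the interferon-type, STING and RNA-sensing list 6 of 22 members rose and 10 fell, in the apoptosis list 14 and 10 of 56, and among pattern recognition receptors 8 and 4 of 30. None of the 3 lists was called by camera (adjusted p = 0.359, 0.359 and 0.464). Suppressor of cytokine signaling 2-like (evm.TU.scaffold15767.29), a feedback inhibitor of cytokine receptor signalling, rose by 1.54 (SE 0.05), and GADD45-type growth arrest and DNA damage-inducible protein (evm.TU.scaffold14907.9) by 1.13 (SE 0.05). Toll-like receptor 4 (evm.TU.scaffold48779.8), a pattern recognition receptor, rose by 0.46 (SE 0.07). Lower were TNF receptor-associated factor 3-like (evm.TU.scaffold64573.12), an adaptor of TNF receptors (-1.22, SE 0.09), NF-kappa-B inhibitor alpha-like (evm.TU.scaffold55943.18), an inhibitor of NF-kappa-B (-0.75, SE 0.10), putative inhibitor of apoptosis (evm.TU.scaffold41437.7) (-1.12, SE 0.06) and interferon-induced protein 44-like (evm.TU.scaffold55531.34) (-1.45, SE 0.14). Omega class glutathione-s-transferase (evm.TU.scaffold1989.72) and Cytochrome P450 2B11 (evm.TU.scaffold40865.8), detoxification enzymes, changed by -1.09 and -0.93. The hemocyte marker peroxidasin homolog (evm.TU.scaffold64279.168) stood at 149 ± 9.09 CPM in PBS, 252 ± 7.01 in LPS_T and 227 ± 5.85 in NOR_T.

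In the exosome and vesicle trafficking list 20 of 112 members rose and 10 fell, and in the phagosome and lysosome list 2 and 14 of 57; neither was called by camera (adjusted p = 0.504 and 0.359). Ras-related protein Rab-7a (evm.TU.scaffold63699.53), a GTPase of late endosomes, changed by -0.45 (SE 0.04) and cathepsin D (evm.TU.scaffold57483.26), a lysosomal protease, by -0.57 (SE 0.07); both calls were lost on unscaled FPKM. Multiple epidermal growth factor-like domains protein 6 (evm.TU.scaffold30275.10) fell from 52.6 ± 5.02 CPM to 23.2 ± 1.21 and 27.9 ± 0.284. Among antimicrobial effectors 3 of 13 rose and 3 fell (camera adjusted p = 0.989). Laccase-3-like (evm.TU.scaffold63699.20), a copper oxidase, changed by -0.66 (SE 0.05) and soma ferritin-like (evm.TU.scaffold63483.25), an iron store, by 0.36 (SE 0.05). The complement and thioester list had 5 of 26 members higher and 3 lower (camera adjusted p = 0.504); leukocyte elastase inhibitor-like (evm.TU.scaffold64243.13), a serpin taken in by the pattern of that list, rose by 0.80 (SE 0.07). Signal transducer and activator of transcription 5B-like (evm.TU.scaffold32463.6), a transcription factor of cytokine signalling, rose by 0.55 (SE 0.05).

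The largest changes were in genes of low level. Arylsulfatase B-like (evm.TU.scaffold27081.3), a lysosomal sulfatase, fell from 13.3 ± 0.403 CPM to 0.373 ± 0.415 and 0.262 ± 0.227 (-5.43, SE 0.53). Ras-related protein Rab-18-B-like (evm.TU.scaffold61329.46), a small GTPase of vesicle traffic, changed by -3.23 (SE 0.23), heme-binding protein 2-like (evm.TU.scaffold48295.56) by -3.40 (SE 0.33) and high mobility group-T protein-like (evm.TU.scaffold32959.6) by -2.43 (SE 0.10). Transcription factor Sp4-like (evm.TU.scaffold29353.1) rose by 2.69 (SE 0.22) and Calpain-9 (evm.TU.scaffold34531.104), a calcium-dependent protease, by 2.88 (SE 0.33). Mucin-5AC-like (evm.TU.scaffold726829.1) reached 46.4 ± 0.619 CPM in LPS_T but 10.9 ± 15 in NOR_T, where 1 library held most of it and several limma settings lost the call. In total 3449 of 11678 genes differed from PBS (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1702 higher and 1747 lower; in limma on unscaled FPKM 1543 were higher and 564 lower. Of the edgeR calls, 615 changed at least 2-fold. Without PBS 1 the count was 3175, of which 2822 were also called with all libraries and in the same direction.

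Libraries titled LPS_T were compared with PBS next. Of 80 members of the ciliated epithelium list, 46 were higher and 4 lower, with a median of 0.69 (camera adjusted p = 1.25e-08; adjusted p = 0.349 with an estimated correlation). Dynein beta chain, flagellar outer arm-like (evm.TU.scaffold34635.4), a motor of the axoneme, went from 7.85 ± 0.579 to 22.6 ± 0.543 CPM, and cilia- and flagella-associated protein 54-like (evm.TU.scaffold37909.9) changed by 1.24 (SE 0.13). In the gonad and gamete list 10 of 35 rose and 3 fell, without a call (camera adjusted p = 0.246); vitellogenin (evm.TU.scaffold25917.13), a yolk protein precursor, rose from 36.0 ± 5.02 to 133 ± 8.97 CPM. These markers of other tissues are given as measured beside the lists that follow. The ER folding list had 10 of 12 members lower (camera adjusted p = 1.25e-08, and 0.266 with an estimated correlation). In the chaperone list 29 of 80 were lower and 10 higher (camera adjusted p = 9.88e-05, and 0.349 with an estimated correlation), with a median of -0.0929. The chaperone median was 0.00375 with library-size scaling only and 0.0675 on unscaled FPKM. There the median of all tested genes moved up too, to 0.13 and 0.17. Ribosomal proteins were lower in 54 of 124 cases and higher in 4 (camera adjusted p = 1.25e-08; adjusted p = 0.459 with an estimated correlation), and the Ribosome term was enriched among lower genes (55 of 111, adjusted p = 3.66e-14). Cell cycle genes were higher in 10 of 27 cases and lower in 0 (camera adjusted p = 0.00139; adjusted p = 0.348 with an estimated correlation). Actin genes were higher in 22 of 46 cases and lower in 2 (camera adjusted p = 0.00154; adjusted p = 0.348 with an estimated correlation).

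Suppressor of cytokine signaling 2-like rose from 260.1 ± 18.6 to 1523 ± 50.3 CPM (2.55, SE 0.06, adjusted p = 1.95e-13) and the GADD45-type gene from 194 ± 12.4 to 689.8 ± 29.8 (1.83, SE 0.06). Tumor necrosis factor receptor superfamily member 5 (evm.TU.scaffold63423.48) rose by 1.09 (SE 0.15) and Galectin-6 (evm.TU.scaffold22817.95), a galactoside-binding lectin, by 1.65 (SE 0.17). Fibrinogen-like protein 1 (evm.TU.scaffold5387.90_evm.TU.scaffold5387.92) changed by -1.0 (SE 0.07). Multiple inositol polyphosphate phosphatase 1-like (evm.TU.scaffold28029.4) rose by 3.87 (SE 0.46). C1q domain-containing protein (evm.TU.scaffold63387.6), of the family of the complement recognition protein C1q, stood at 3.34 ± 0.0586 CPM against 0.0570 ± 0.0988 in PBS, and beta-1,3-galactosyltransferase 5-like (evm.TU.scaffold57483.17) at 4.69 ± 0.975 against 0.0570 ± 0.0988. Epididymal secretory protein E1 (evm.TU.scaffold64243.5) had no count in any LPS_T library and 2.40 ± 0.621 CPM in PBS, so it was at least 8.92-fold lower, against a floor of 3 fragments per library. Protein MB21D2-like (evm.TU.scaffold47499.11) changed by -3.52 (SE 0.32) and BTB/POZ domain-containing protein KCTD6 (evm.TU.scaffold12539.1) by -3.80 (SE 0.50). Higher genes were enriched for caspase-type peptidases (19 of 33, adjusted p = 5.98e-04). In all, 3855 genes differed, 2085 higher and 1770 lower, 1028 of them at least 2-fold; in limma on unscaled FPKM 1883 were higher and 584 lower, and in edgeR without PBS 1 the counts were 1868 and 1811.

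Signal transducer and activator of transcription 5B-like stood at 276 ± 8.23 CPM in LPS_T and 157 ± 9.02 in PBS (0.81, SE 0.06), and a gene named interferon-induced protein 44-like (evm.TU.scaffold49157.2) rose by 1.58 (SE 0.15). Tetraspanin-18-like (evm.TU.scaffold56263.3), of a family of membrane proteins found on vesicles, rose by 1.19 (SE 0.09). Cytochrome P450 27C1-like (evm.TU.scaffold55147.16), a cytochrome P450 enzyme, went from 7.24 ± 0.657 to 31.1 ± 3.09 CPM. Neuropeptide S receptor-like (evm.TU.scaffold9805.18) rose from 920.4 ± 7.58 to 3103 ± 141 CPM (1.75, SE 0.06); its list, of nerve markers, was not called (camera adjusted p = 0.246). DNA topoisomerase 2-alpha-like (evm.TU.scaffold20057.4), an enzyme of chromosome segregation, rose by 0.50 (SE 0.08). In the glycolysis list 4 of 21 members fell and 2 rose (camera adjusted p = 0.456), with hexokinase type 2-like (evm.TU.scaffold31741.5) at -0.63 (SE 0.08). Probable acyl-CoA dehydrogenase 6 (evm.TU.scaffold26649.14) rose by 1.26 (SE 0.09).

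In libraries titled NOR_T, 37 of 80 members of the ciliary list were lower than in PBS and 3 higher, with a median of -0.56 (camera adjusted p = 1.64e-08; adjusted p = 0.548 with an estimated correlation). Dynein heavy chain 7, axonemal-like (evm.TU.scaffold59337.30) went from 18.1 ± 2.95 to 4.73 ± 0.545 CPM and cilia- and flagella-associated protein 57-like (evm.TU.scaffold59003.17) from 18.5 ± 1.40 to 7.15 ± 1.10. In the gonad list 13 of 35 fell and 1 rose (camera adjusted p = 0.0624, and 0.0138 without PBS 1, where it is called; adjusted p = 0.593 with an estimated correlation over all libraries). Tubulin alpha chain, testis-specific (evm.TU.scaffold64139.6) fell from 699 ± 80.0 to 295 ± 14.5 CPM, and testis-specific serine/threonine-protein kinase 3-like (evm.TU.scaffold34635.13) from 15.7 ± 3.71 to 3.38 ± 0.665. Beside these markers, the ER folding list had 6 of 12 members lower (camera adjusted p = 0.00280; adjusted p = 0.548 with an estimated correlation), and calnexin-like (evm.TU.scaffold61185.19), another ER chaperone, changed by -0.74 (SE 0.12). Both calls were lost on unscaled FPKM (for the list, camera adjusted p = 0.195), and that of the list with library-size scaling only (0.0719). All 8 chaperonin subunits were lower, by -1.25 to -1.06. Actin genes were higher in 14 of 46 cases and lower in 4 (camera adjusted p = 0.00115; adjusted p = 0.491 with an estimated correlation), with profilin-like at 0.92 (SE 0.06). Not called were ribosomal proteins, 10 of 124 lower and 2 higher with a median of -0.0652 (camera adjusted p = 0.162; 0 higher and 0 lower adjusted over the list alone), the cell cycle list, 3 of 27 higher and 1 lower (0.206), and the chaperone list, 23 of 80 lower and 15 higher (0.196).

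In the interferon-type list 10 of 22 genes fell and 6 rose, without a call (camera adjusted p = 0.196). Interferon regulatory factor 2-like (evm.TU.scaffold27749.7), a transcription factor, stood at 14.2 ± 1.74 CPM against 40 ± 3.03 in PBS and 41.7 ± 2.71 in LPS_T. Peptidoglycan-recognition protein SC2-like (evm.TU.scaffold60745.5), which binds bacterial cell walls, rose by 3.15 (SE 0.41). Arginine kinase (evm.TU.scaffold60199.9), an enzyme of energy buffering and a muscle marker here, stood at 6.84 ± 0.523 CPM in NOR_T and 0.366 ± 0.326 in PBS, and Zinc finger RNA-binding protein (evm.TU.scaffold722165.1) at 5.85 ± 1.70 and 0.167 ± 0.190. HRAS-like suppressor 2 (evm.TU.scaffold24287.4) changed by -3.42 (SE 0.31). Tubulin beta-4B chain-like (evm.TU.scaffold63991.2) and Collagen alpha-5(VI) chain (evm.TU.scaffold56559.2) had no count in any NOR_T library and were at least 28.2-fold and 18.9-fold lower than in PBS. Lower genes were enriched for microtubules (28 of 83, adjusted p = 1.08e-04) and arachidonic acid metabolism (19 of 58, adjusted p = 0.00616). In all, 2903 genes differed, 1331 higher and 1572 lower, 835 of them at least 2-fold. The majority turned in limma on unscaled FPKM, with 778 higher and 565 lower, and with library-size scaling only, with 1080 and 924. In these settings the median of all tested genes moved from -0.00211 to 0.12 and 0.0779.

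In the autophagy list 3 of 17 members rose and 3 fell (camera adjusted p = 0.460). Sequestosome-1-like (evm.TU.scaffold11599.5), a receptor for autophagy cargo, rose from 857 ± 56.1 to 1405 ± 85.7 CPM (0.71, SE 0.06). Early growth response protein 1-B-like (evm.TU.scaffold10271.2), an immediate-early transcription factor, rose by 0.55 (SE 0.07). A gene named putative inhibitor of apoptosis (evm.TU.scaffold41437.6), on the scaffold of the one described above, rose by 0.82 (SE 0.06). A gene named toll-like receptor 4 (evm.TU.scaffold32959.29) rose by 2.22 (SE 0.32). Arachidonate 5-lipoxygenase-like (evm.TU.scaffold8265.3), an enzyme of leukotriene synthesis, changed by -0.69 (SE 0.07) and acidic phospholipase A2-like (evm.TU.scaffold47297.49), which releases fatty acids from phospholipids, by 1.01 (SE 0.13). Probable phosphoglycerate kinase (evm.TU.scaffold19831.18), of glycolysis, rose by 0.51 (SE 0.09) and neuronal acetylcholine receptor subunit alpha-3-like (evm.TU.scaffold27033.1) by 1.90 (SE 0.25).

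The 2 exosome groups shared many changes against PBS. There were 848 genes higher in both and 821 lower in both, where independent lists would share 238 and 238. Across genes, which are not independent replicates, the covariance of the fold changes was 0.289 against 0.0582 on average in 20 simulations of 3 unchanged groups, and their correlation 0.432 against 0.519. The 3 PBS libraries cannot be split into parts of 2, so part of the excess may come from the shared controls. A further 272 genes were called in opposite directions, where independent lists would share 482. Of these, 237 were higher in LPS_T and lower in NOR_T (281 expected) and 35 the reverse (202 expected). Shared PBS libraries alone gave a mean correlation of 0.519 in the simulations. Fewer opposite calls than for independent lists may therefore also come from them.

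**Figure D3:**
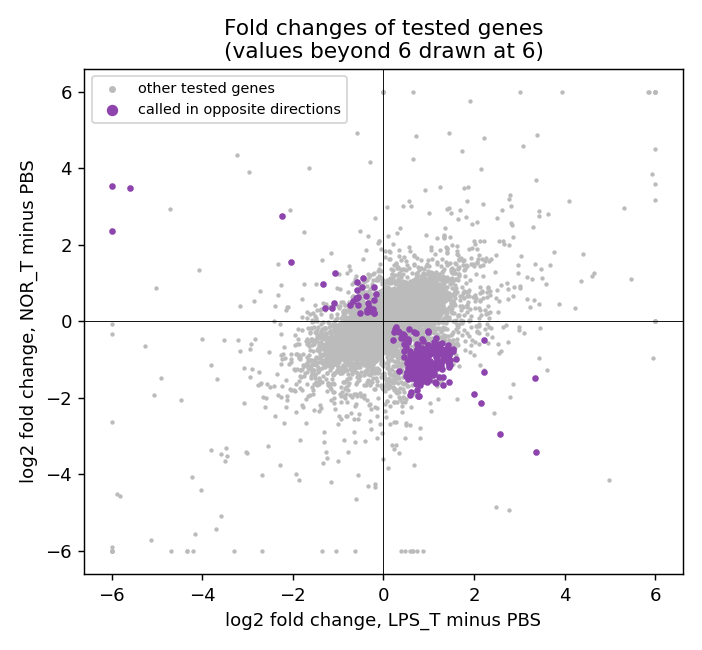
Log2 fold changes of the 11678 tested genes in LPS_T (horizontal) and NOR_T (vertical) against PBS, 1 point per gene, with values beyond 6 drawn at 6. The 272 coloured genes were called in opposite directions, and 237 of them lie at the lower right.

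The direct comparison of LPS_T with NOR_T tests whether the libraries of the 2 groups differ, whatever the cause. Of the 29 lists, the ciliary one had the smallest camera p: 50 of 80 were higher in LPS_T and 0 lower, with a median of 1.29 (camera adjusted p = 2.77e-24; adjusted p = 0.187 with an estimated correlation). Dynein heavy chain 7, axonemal-like stood at 31.3 ± 2.27 CPM in LPS_T and 4.73 ± 0.545 in NOR_T (2.73, SE 0.15). In the gonad list 16 of 35 were higher and 3 lower, with a median of 0.61 (camera adjusted p = 1.06e-04; adjusted p = 0.190 with an estimated correlation). Tubulin alpha chain, testis-specific differed by 1.98 (SE 0.08, adjusted p = 8.91e-11) and testis-specific serine/threonine-protein kinase 3-like by 2.62 (SE 0.20). Lower in LPS_T were 8 of 12 members of the ER list (camera adjusted p = 1.87e-07; adjusted p = 0.187 with an estimated correlation) and 24 of 80 of the chaperone list, with 7 higher (camera adjusted p = 1.06e-04; adjusted p = 0.261 with an estimated correlation). Heat shock 70 kDa protein (evm.TU.scaffold44765.1) differed by -1.12 (SE 0.06) and heat shock protein 68-like (evm.TU.scaffold2569.5) by -0.99 (SE 0.06). All 8 chaperonin subunits were lower in LPS_T, by -0.59 to -0.20; with library-size scaling only, 6 of them were called.

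**Figure D4:**
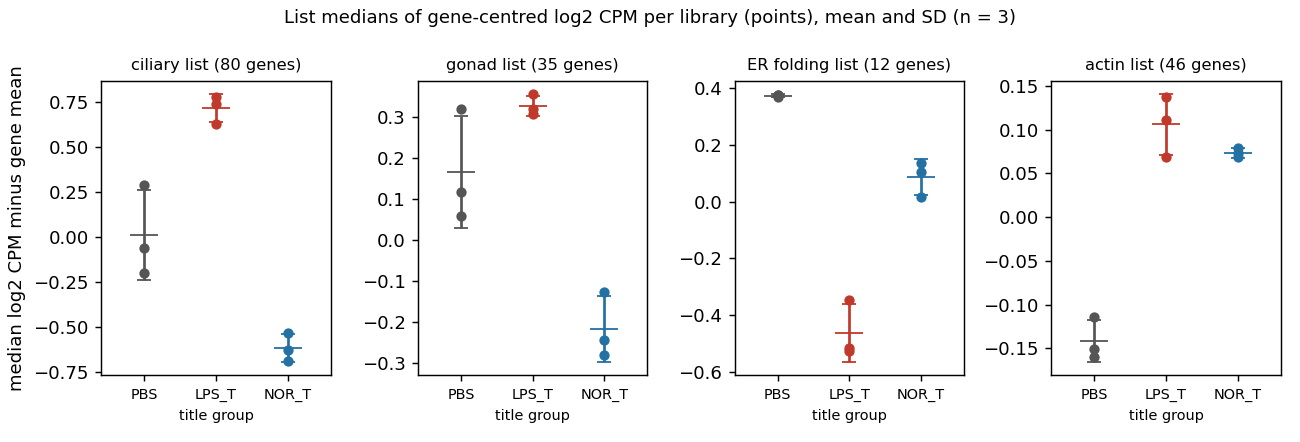
Median over the members of 4 gene lists of log2 CPM minus each gene's mean over the 9 libraries, per library (points), with the mean and SD of each title group (n = 3). For the ciliary list LPS_T minus NOR_T had a median log2 change of 1.29, and for the ER folding list -0.59.

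Suppressor of cytokine signaling 2-like was higher in LPS_T by 2.02 (SE 0.06) and interferon regulatory factor 2-like by 1.56 (SE 0.11). Cell cycle genes were higher in 5 of 27 cases (camera adjusted p = 0.0463; adjusted p = 0.445 with an estimated correlation), among them G2/mitotic-specific cyclin-B-like (evm.TU.scaffold40559.6) at 0.79 (SE 0.10). Ribosomal proteins were lower in 16 of 124 cases and higher in 1 (camera adjusted p = 2.46e-06; adjusted p = 0.641 with an estimated correlation); without PBS 1, 40 were lower. 60S ribosomal protein L19-like (evm.TU.scaffold25473.19) differed by -0.26 (SE 0.06), a call lost on unscaled FPKM and with library-size scaling only. The call of the cell cycle list was lost under 9 other settings (camera adjusted p from 0.0502 to 0.121), among them those without PBS 1 (0.0570), LPS_T 2 (0.0625), NOR_T 1 (0.0831) and NOR_T 3 (0.0864). The shell and mantle list had 3 of 7 members lower (camera adjusted p = 0.0463; adjusted p = 0.261 with an estimated correlation); without PBS 1, LPS_T 1, NOR_T 1 and NOR_T 2 its adjusted p was 0.0608, 0.0621, 0.0800 and 0.0834, and over all 8 settings that lost the call it was 0.0502 to 0.112. Perlucin-like protein (evm.TU.scaffold11019.3) differed by -1.05 (SE 0.11), and another gene of that name (evm.TU.scaffold23219.2) had no count in LPS_T or PBS and was at least 12.2-fold lower in LPS_T than in NOR_T. The interferon-type list was not called (camera adjusted p = 0.0609), with 8 of 22 genes higher and 1 lower. N-acetylneuraminate lyase B-like (evm.TU.scaffold63187.36) and Epididymal secretory protein E1 had no count in LPS_T and were at least 10.1-fold and 7.13-fold lower there. Tubulin beta-4B chain-like and Collagen alpha-5(VI) chain, without a count in NOR_T, were at least 18.7-fold and 9.22-fold higher in LPS_T. Terms enriched among genes lower in LPS_T included the spliceosome (31 of 130, adjusted p = 6.96e-05) and protein processing in the ER (38 of 146, adjusted p = 4.38e-07), and among higher ones the extracellular matrix (12 of 28, adjusted p = 0.00210).

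Sequestosome-1-like differed between LPS_T and NOR_T by -0.88 (SE 0.06) and early growth response protein 1-B-like by -0.75 (SE 0.07). The inhibitor of apoptosis gene evm.TU.scaffold41437.6 differed by -1.41 (SE 0.06), while baculoviral IAP repeat-containing protein 2-like (evm.TU.scaffold62537.1) stood at 21.3 ± 1.79 CPM in LPS_T and 6.65 ± 0.586 in NOR_T. Cytochrome P450 27C1-like differed by 1.75 (SE 0.13), signal transducer and activator of transcription 5B-like by 0.53 (SE 0.06), a call lost with a smaller pseudocount on unscaled FPKM, and neuropeptide S receptor-like by 1.38 (SE 0.06). ATP-dependent 6-phosphofructokinase-like (evm.TU.scaffold25473.20), a rate-limiting enzyme of glycolysis, differed by -0.68 (SE 0.10). Zygotic DNA replication licensing factor mcm3-like (evm.TU.scaffold62691.6), part of the DNA replication helicase, differed by 0.75 (SE 0.14). Actin, cytoplasmic 1-like (evm.TU.scaffold63197.2) stood at 91.1 ± 4.75 CPM in LPS_T, 29.2 ± 3.18 in NOR_T and 71.9 ± 12.9 in PBS.

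In all, 2509 genes differed between LPS_T and NOR_T, 1471 higher in LPS_T and 1038 lower, 993 of them at least 2-fold. The excess of higher calls depended on the setting. Without PBS 1, 3099 were called, 1586 higher and 1513 lower, and with limma after quantile normalization 1311 were higher and 1242 lower. On unscaled FPKM these were 1057 and 356, and with library-size scaling only 1223 and 491. In the 4 contrasts, 5, 6, 3 and 7 of 29 lists were called with the preset correlation (in the order both groups against PBS, LPS_T against PBS, NOR_T against PBS, LPS_T against NOR_T). With a correlation estimated per list, 0 were called in each contrast by camera; at an unadjusted p under 0.05 these were 2, 3, 1 and 4. The directional test of fry, which does not compare a list with other genes, called 17, 20, 15 and 13.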

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

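All tests of explanations and all counts over other splits of the libraries were chosen after the result they bear on had been seen; the tests of each gene and list were planned.

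The lists of ciliary and of gamete markers had medians above 0 for LPS_T against NOR_T, 1.29 and 0.61. A lower share of hemocytes in LPS_T, filled by all other tissues alike, would raise low-level markers of each. Low-level means a mean under 20 CPM in NOR_T, a group of this contrast, so the choice can itself raise such medians. The highest low-level median among the muscle, digestive gland, nerve and shell lists was 0.0547 (nerve, bootstrap interval -0.43 to 0.39). That of low-level ciliary genes was 1.43 (0.87 to 1.77). Over all members, the medians were 1.29 (ciliary), -0.03 (muscle), -0.13 (digestive gland), -0.12 (nerve) and -0.47 (shell). These values argue against such an even rise, but the 4 low-level shell genes (-1.05, -9.97 to 1.19) leave their list undecided. Added tissue of 1 kind would also lower the share of hemocytes, and flat lists of other tissues cannot exclude it. If ciliated epithelium were the only source, the gamete list was predicted to stay unmoved. The list had a median of 0.61 (bootstrap interval over genes, which are not independent, 0.06 to 1.36). This does not decide the question, because without the germ genes named next its other 25 members had a median of 0.16. Of 12 meiosis genes and testis kinases 12 were higher in LPS_T, with a median of 1.66 (1.34 to 2.5); they were chosen with the pattern in view, 10 of them from the gamete list, whose other 25 members had 6 higher and 3 lower, with a median of 0.16. Male germ cells carried along in unequal amounts may account for both groups of genes. Vitellogenin, a yolk protein precursor in the gamete list, was also higher in LPS_T (1.08), and a male source for it was not tested. Against PBS, the median in NOR_T was -1.15 for these 12 germ genes and -0.56 for the ciliary ones, a difference of -0.59 (-1.29 to -0.20). In LPS_T the medians were 0.59 and 0.69, with no difference detected (-0.10, -0.54 to 0.07). Not every germ gene was higher there, as meiotic recombination protein SPO11-like stood at 1.28 CPM in LPS_T and 1.35 in PBS. Germ cells and ciliated epithelium, alone or together, stay open. The criterion for germ cells, which they first met, was made stricter after that outcome. The test of ciliated epithelium was moved from the 12 genes to the whole list. A stricter bound also tried, an interval above 0.5, was not met. An effect of the injected vesicles was not tested apart from these tissues.

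PBS 1 stood apart from the other PBS libraries. Leaving it out kept 81.8% of the calls of both exosome groups against PBS, with the same sign, which argues against that library alone behind them. Leaving out the 2 genes of scaffold38697 that took many of its counts kept 96.2%. What set PBS 1 apart stays open.

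The chaperonin subunits were lower in both exosome groups. For the mean of both groups against PBS, the least changed subunit was still at -1.06 with library-size scaling, -1.17 with RLE scaling and -1.13 without PBS 1. For NOR_T against PBS it was at -0.965 with library-size scaling, -1.06 with RLE scaling and -0.971 without PBS 1, which argues against scaling or that library as the whole cause. An effect of injected vesicles, or of any other difference between the injected groups and PBS, stays open and was not tested.

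For both exosome groups against PBS, 1 of 100 drawn splits of the 9 libraries, the real one, gave as many as 3449 genes. The highest other count was 1776. Draws that mix unlike title groups widen the spread within each drawn group, and libraries may not be separate animals. The splits therefore cannot exclude chance between animals or pools. The highest other counts follow the title groups: 1716 and 1776 with the PBS libraries kept together and the exosome libraries mixed, 1751 with all LPS_T libraries in the place of PBS and 580 with all NOR_T libraries there. In the 95 draws with libraries of different title groups in that place the highest was 96. The 10 splits of 3 against 3 are too few for a share under 0.05, with 1 of 10 as large in each: 3855 genes against a highest other count of 0 (LPS_T against PBS), 2903 genes against a highest other count of 0 (NOR_T against PBS) and 2509 genes against a highest other count of 1 (LPS_T against NOR_T).

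The changes of the exosome groups against PBS differed from each other in the results that follow, by the direct edgeR test of LPS_T against NOR_T or, for lists, by camera. 272 genes were called in opposite directions against PBS. The lists had median log2 differences of -0.21 (heat shock proteins and chaperones), -0.59 (ER stress and protein folding), 0.23 (cell cycle and DNA replication), -0.14 (ribosomal proteins), 1.29 (markers: ciliated epithelium (gill, mantle)), 0.61 (markers: gonad and gametes) and -0.47 (markers: shell and mantle secretion). These list calls rest on the preset correlation: with an estimated one none of the 7 was called (adjusted p from 0.187 to 0.641). The cell cycle list also lost its call under 9 other settings and the shell list under 8.

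Higher in LPS_T on the log2 scale were suppressor of cytokine signaling 2-like (2.02), growth arrest and DNA damage-inducible protein GADD45 alpha-like (1.41), signal transducer and activator of transcription 5B-like (0.53), high mobility group-T protein-like (0.45), mucin-5AC-like (2.07) and dynein beta chain, flagellar outer arm-like (0.47). Also on that side lay cilia- and flagella-associated protein 54-like (1.96), vitellogenin (1.08), Tumor necrosis factor receptor superfamily member 5 (0.72), Galectin-6 (1.94), multiple inositol polyphosphate phosphatase 1-like (3.43) and C1q domain-containing protein (4.38). To these add beta-1,3-galactosyltransferase 5-like (6.89), tetraspanin-18-like (0.75), cytochrome P450 27C1-like (1.75), neuropeptide S receptor-like (1.38), DNA topoisomerase 2-alpha-like (0.30) and probable acyl-CoA dehydrogenase 6 (0.87). Also on that side lay dynein heavy chain 7, axonemal-like (2.73), cilia- and flagella-associated protein 57-like (2.23), tubulin alpha chain, testis-specific (1.98), testis-specific serine/threonine-protein kinase 3-like (2.62), interferon regulatory factor 2-like (1.56) and HRAS-like suppressor 2 (2.15). To these add G2/mitotic-specific cyclin-B-like (0.79), baculoviral IAP repeat-containing protein 2-like (1.68), zygotic DNA replication licensing factor mcm3-like (0.75), actin, cytoplasmic 1-like (1.64) and interferon-induced protein 44-like (evm.TU.scaffold49157.2) at 0.82.

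Lower in LPS_T on the log2 scale were T-complex protein 1 subunit theta-like (-0.59), 78 kDa glucose-regulated protein-like (-0.76), calreticulin-like (-0.96), 40S ribosomal protein S19 (-0.23), putative inhibitor of apoptosis (evm.TU.scaffold41437.7) at -0.55 and ras-related protein Rab-7a (-0.22). Also on that side lay cathepsin D (-0.37), laccase-3-like (-0.41), fibrinogen-like protein 1 (-0.61), protein MB21D2-like (-3.04), calnexin-like (-0.69) and peptidoglycan-recognition protein SC2-like (-2.58). To these add Arginine kinase (-5.66), Zinc finger RNA-binding protein (-7.41), sequestosome-1-like (-0.88), early growth response protein 1-B-like (-0.75), acidic phospholipase A2-like (-0.99) and probable phosphoglycerate kinase (-0.33). Also on that side lay heat shock 70 kDa protein (-1.12), heat shock protein 68-like (-0.99), 60S ribosomal protein L19-like (-0.26), perlucin-like protein (evm.TU.scaffold11019.3) at -1.05, ATP-dependent 6-phosphofructokinase-like (-0.68) and putative inhibitor of apoptosis (evm.TU.scaffold41437.6) at -1.41. To these add toll-like receptor 4 (evm.TU.scaffold32959.29) at -0.88, FMRFamide receptor-like (-0.66), neurotrypsin-like (evm.TU.scaffold38493.30) at -0.72 and Krueppel-like factor 3 (-0.25). Epididymal secretory protein E1 was at least 7.13-fold lower in LPS_T than in NOR_T. Tubulin beta-4B chain-like was at least 18.7-fold higher in LPS_T than in NOR_T. Collagen alpha-5(VI) chain was at least 9.22-fold higher in LPS_T than in NOR_T. Perlucin-like protein (evm.TU.scaffold23219.2) was at least 12.2-fold lower in LPS_T than in NOR_T. N-acetylneuraminate lyase B-like was at least 10.1-fold lower in LPS_T than in NOR_T. The fitted changes of beta-1,3-galactosyltransferase 5-like, C1q domain-containing protein, Arginine kinase and Zinc finger RNA-binding protein rest on groups near 0 and depend on the prior count. Without 1 library at a time, chosen after seeing the data, 7 of these 62 genes lost the call of LPS_T against NOR_T. Mucin-5AC-like, whose NOR_T level lies mostly in NOR_T 1, lost it without LPS_T 1, LPS_T 2, LPS_T 3, NOR_T 2 or NOR_T 3 (adjusted p from 0.0723 to 0.0994), and differed by 4.37 without NOR_T 1. The call was also lost for toll-like receptor 4 (evm.TU.scaffold32959.29) without LPS_T 1, LPS_T 2, LPS_T 3, NOR_T 1, NOR_T 2 or NOR_T 3 (adjusted p from 0.0639 to 0.169), high mobility group-T protein-like without LPS_T 3 or NOR_T 3 (adjusted p from 0.0749 to 0.0918), dynein beta chain, flagellar outer arm-like without LPS_T 3 or NOR_T 2 (adjusted p from 0.0517 to 0.0740), DNA topoisomerase 2-alpha-like without LPS_T 2 (adjusted p = 0.0510), probable phosphoglycerate kinase without LPS_T 3 (adjusted p = 0.0528) and Krueppel-like factor 3 without LPS_T 3 (adjusted p = 0.0552). Beta-1,3-galactosyltransferase 5-like moved to 10.47 without NOR_T 3.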

How the results depend on the processing

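Library-size scaling only, RLE scaling, the fit without both scaffold38697 genes, counts divided by counts per fragment and the genes called in opposite directions were added after seeing the data. In the order both exosome groups, LPS_T and NOR_T against PBS, then LPS_T against NOR_T, 3449, 3855, 2903 and 2509 genes were called. The gene results and lists counted next were picked from these same data for large changes, small adjusted p or a call. That choice favours keeping the call, so the counts do not describe all genes. Of 3859 comparisons of 167 gene results with another setting, 3755 kept direction and side of the threshold, 104 lost the call and 0 reversed. Of 524 for 21 called lists, 461 were kept, 46 lost the call and 17 had a median of the other sign. Several of the changed signs came from settings that also moved the median of all genes. In simulated data with 66 genes changed by 0.5 on the log2 scale, 31.8% of them were recovered for LPS_T against PBS. Unless said otherwise, the cause was not tested.

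Limma on unscaled log2(FPKM + 1) called 2107, 2467, 1343 and 1413 genes, 665 in the same direction in both groups and 120 in opposite ones. With a pseudocount of 0.1 these were 1841, 2172, 1212 and 1211, 602 and 98, and without an intensity trend 1982, 2350, 1263 and 1384, 613 and 114. Library-size scaling only left 1064 genes in the same direction. The share of higher calls was 49.3%, 54.1%, 45.8%, 58.6% in the same order of contrasts, 73.2%, 76.3%, 57.9%, 74.8% on unscaled FPKM, 73.0%, 75.6%, 56.6%, 75.0% with the pseudocount of 0.1, 72.5%, 76.5%, 56.6%, 76.1% without the trend and 64.1%, 69.4%, 53.9%, 71.4% with library-size scaling only. For LPS_T against NOR_T it was 51.2% without PBS 1 and 51.4% with quantile normalization. The median of all genes, 0.00433, 0.0271, -0.00211, -0.00470, moved to 0.15, 0.17, 0.12, 0.0179 on unscaled FPKM, 0.18, 0.21, 0.16, 0.0223 with the smaller pseudocount and 0.0978, 0.13, 0.0779, 0.0215 with library-size scaling only. By their construction these settings do not correct for the few genes that took many counts in PBS 1. PBS 1 is not a library of LPS_T against NOR_T, though in the main fit it enters the TMM scaling and the shared spread. Leaving it out of that fit moved the median of all genes in this contrast to -0.0351. The cause of the shift in this contrast under the other settings was not tested.

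A fold change of at least 2, by its construction, left 615, 1028, 835 and 993 genes. With a mean FPKM of at least 5, fewer genes were tested and 1508 were called between LPS_T and NOR_T, 153 in opposite directions against PBS, and 5 lists for NOR_T against PBS. Library weights left 3 lists for both exosome groups against PBS. An estimated correlation left 0, 0, 0 and 0 lists in camera, and fry called 17, 20, 15 and 13.

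The median of all genes rose on unscaled FPKM and with library-size scaling only, as given above. A list median that changed sign there may show that shift alone. The list medians that changed sign are these. For the median of heat shock proteins and chaperones, both exosome groups vs PBS (-0.00253), it was 0.13 (limma on log2(FPKM + 1)), 0.18 (limma, pseudocount of 0.1), 0.0633 (no filter on low values), 0.00362 (limma, FPKM scaled by TMM), 6.83e-04 (replicate block), 0.13 (limma, eBayes without trend), 0.00949 (limma, library weights), 0.0779 (edgeR, library-size scaling only), 0.0362 (without PBS replicate 1), 6.74e-04 (without LPS_T replicate 3). For the median of ribosomal proteins, both exosome groups vs PBS (-0.14), it was 0.0243 (limma on log2(FPKM + 1)), 0.0254 (limma, pseudocount of 0.1), 0.0243 (limma, eBayes without trend). For the median of heat shock proteins and chaperones, LPS_T vs PBS (-0.0929), it was 0.0675 (limma on log2(FPKM + 1)), 0.0957 (limma, pseudocount of 0.1), 0.0675 (limma, eBayes without trend), 0.00375 (edgeR, library-size scaling only).

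Without 1 library at a time the counts ranged over 2889 to 3289, 3110 to 3861, 2256 to 2814 and 1963 to 3099 genes, 1329 to 1547 in the same direction, 194 to 253 in opposite ones, 3 to 5, 6 to 7, 3 to 5 and 5 to 8 lists, and 99 to 138 terms. With the replicate number as a block, 3331, 3755, 2793 and 2423 genes were called. Deviations from the group means correlated between -0.02 and 0.08 for libraries sharing a number and between -0.10 and 0.07 for others. These values gave no clear sign of shared animals, pools or days, but with so few libraries per group they cannot exclude them. DESeq2 called 3684, 4059, 3155 and 2806 genes. The list median of heat shock proteins and chaperones for both exosome groups against PBS ranged from -0.0363 to 0.0362 without 1 library.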

Other observations

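FMRFamide receptor-like (evm.TU.scaffold57011.25), a receptor of a neuropeptide, stood at 175 ± 9.92 CPM in PBS, 93.3 ± 6.95 in LPS_T and 147 ± 3.88 in NOR_T, while neuropeptide S receptor-like rose by 1.06 (SE 0.05) in the mean of both exosome groups. The term neuropeptide signaling pathway was enriched among genes lower in the mean of both exosome groups (13 of 19, adjusted p = 3.68e-05). By single group against PBS it was called in LPS_T (13 of 19, Fisher's exact test, adjusted p = 5.65e-05) and not in NOR_T. Neurotrypsin-like (evm.TU.scaffold38493.30), a secreted protease in the digestive gland list, went from 1272 ± 77.3 CPM to 472 ± 6.86 and 777 ± 25.6, and Krueppel-like factor 3 (evm.TU.scaffold57011.109), a transcription factor, from 663 ± 60.7 to 434 ± 25.8 and 515 ± 24.4. GATA-binding factor (evm.TU.scaffold58571.9), a transcription factor in the hemocyte list, rose by 0.44 (SE 0.07).

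For the lists not described so far, the numbers of members higher and lower in the mean of both exosome groups than in PBS, then in LPS_T than in NOR_T, were as follows, each with the camera adjusted p, and no such list was called in either contrast. TLR, NF-kB and MAPK signalling, 1 and 4 of 21 (0.646), then 1 and 0 (0.854). Cytokines and cytokine receptors, 2 and 4 of 16 (0.994), then 5 and 2 (0.718). Antioxidant and detoxification, 22 and 33 of 112 (0.359), then 14 and 5 (0.818). Autophagy, 4 and 4 of 17 (0.504), then 1 and 1 (0.954). Immediate-early stress genes, 6 and 4 of 19 (0.464), then 4 and 4 (0.818). Oxidative phosphorylation, 1 and 7 of 56 (0.504), then 1 and 2 (0.168). Glycolysis and glucose metabolism, 3 and 5 of 21 (0.646), then 2 and 3 (0.197). Lipid metabolism, 8 and 4 of 44 (0.504), then 6 and 3 (0.854). Proteasome and ubiquitin, 8 and 4 of 78 (0.504), then 2 and 2 (0.197). Histones, 1 and 1 of 12 (0.989), then 3 and 0 (0.818). Markers of muscle, 10 and 4 of 38 (0.199), then 3 and 3 (0.818). Markers of digestive gland, 4 and 7 of 17 (0.199), then 2 and 4 (0.494). Markers of nerve and neurosecretion, 2 and 9 of 20 (0.464), then 2 and 6 (0.361). Markers of hemocytes, 2 and 1 of 5 (0.504), then 0 and 1 (0.854).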
